A study of Homo sapiens with 6 samples.

How the data were processed

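Gene expression was measured by RNA-seq in 6 libraries, 1 for each of 6 groups: an untreated control, NaPhen, PFI, PR20, PR20-NaPhen and PR20-PFI. The labels gave the line as NSC-34, the organism as human, 15% serum in the medium, and an input of 1 µg of RNA with an integrity number above 9. They gave compound at 10 µM for 48 h alone or for 24 h before PR20, and PR20 at 5 µM for 24 h, and did not say whether a compound stayed in the medium during PR20. No replicates were listed, so each group rested on 1 library.

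The authors aligned the reads with STAR (2.5.3 per the labels, 2.5 per the file headers) and counted them per gene. The labels named GRCh38, while the headers of the fold-change tables named a mouse annotation (Gencode M16, Ensembl 91); all identifiers in the tables were human, and positions here are from GENCODE 29 on GRCh38. The deposited count table held read counts that the authors had divided by the DESeq2 size factor of each library, rounded to 1 decimal. In the 5 deposited fold-change tables, each of 1 treated library against the control, the authors gave the mean normalized count, the log2 fold change from DESeq2, its standard error on the log2 scale, and a Wald p-value with a Benjamini-Hochberg adjusted p-value over 27703 genes. In the deposited table for PFI the column headed as a standard error held a score instead, the Wald statistic of the authors' DESeq2 test, since 12932 of its values were negative and it gave the p-value column within 8.8e-10. Among genes with a normalized count above 20 in both libraries of a comparison (12755 to 13464 genes per table), the log2 fold changes of those tables differed from log2 ratios of the deposited normalized counts by at most 0.006; the other genes were not compared.

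Reads were recovered by finding for each library the factor that turns its normalized counts into whole numbers. The factors ran from 0.9089 to 1.0818, and between 99.92% and 100% of the values up to 1000 were whole within a tolerance of 0.05 normalized counts. The recovered totals were 13308986 to 15339615 reads. Of 27703 deposited gene rows 27580 were matched to the annotation by identifier, and 12 sex-linked genes were left out before any table was made, which kept 27691.

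The recovered whole reads served limma-voom, TMM scaling, library totals, and the ratios, counting intervals, list medians and summed counts of single libraries. The planned edgeR and DESeq2 tests of read counts were not run, because the deposited table held normalized counts. Limma was used in their place, on log2(normalized count + 1) with a trended prior (limma-trend, 6.6 prior degrees of freedom), with additive terms for compound (none, NaPhen, PFI) and PR20 over 6 libraries, which leaves 2 residual degrees of freedom. The PR20 effect rests on 3 pairs of libraries, each compound effect on 2, and any departure from additivity counts as error. Genes needed a normalized count of at least 10 in at least 2 libraries (16269 genes), and calls were made at a Benjamini-Hochberg adjusted p under 0.05. The deposited scaling was used in place of the planned TMM, which became an alternative.

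A set of 36 gene lists was fixed before the data were examined, with the comparisons and the rule for named genes. Lists were tested with camera at the preset correlation of 0.01 and with an estimated correlation, adjusted over the 36 lists within each effect. Each treated library was set against the control by log2 ratio with an exact 95% counting interval from recovered reads (binomial, Clopper-Pearson); genes counted as different had a ratio of at least 2-fold, an interval that excluded 1.5-fold and a mean count of at least 20. For 0 reads the bound used a floor of 3 reads in that library. List medians were placed among 10000 random lists of like size and mean expression, with the tails at 2.5 and 97.5. Genes of a random list were drawn independently, while members of a gene list can move together, so a place in a tail is not a test. The PR20 response was compared between pairs by choosing genes in 1 pair and measuring them in the other two, with 95% intervals from 1000 resamples of genes, which are not independent. No p-value was computed across genes for these slopes, ratios and medians. The response of each pair was also tested against the mean of the other two, with limma and with camera, by adding a PR20 term for that pair to the additive fit; this leaves 1 residual degree of freedom and assumes that the other two pairs respond alike.

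Named genes followed a rule: per effect, among genes with a mean count of at least 50, an adjusted p under 0.05 and the same direction in every pair, the 8 largest rises and 8 largest falls; per list described, up to 4 members with the largest absolute log2 fold change and a mean count of at least 50, passing or not; per library, the 5 largest ratios each way with a mean count of at least 50 in the pair; and for NaPhen minus PFI the 4 largest each way. Genes without a descriptive symbol, pseudogenes and sex-linked genes were skipped. A few genes that the rule takes are left out of the text. Genes named outside the rule are marked in the text as chosen after their values were seen.

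The steps were tested on simulated data. With a dispersion of 0.01 limma recovered 96% of 2-fold PR20 changes and 89% of 2-fold NaPhen changes, and with a dispersion of 0.04 it recovered 70% and 40%; 4-fold changes were recovered at 96% or more in every setting, with 4 to 10 false calls among 15970 to 16034 genes. The list test, with the preset correlation and an unadjusted camera p under 0.05, found 6 of 6 shifted lists and 0 of 6 unshifted lists. The simulated genes were independent of each other. In the data the estimated correlation was 0.849 for DNA replication and 0.921 for mitosis, so lists whose members move together were not covered. The 2-fold rule recovered 93% of 4-fold changes with 1 false call among 14010 genes, and a response of 0.5 was returned as 0.5. Among random lists, a simulated list shifted by 0.5 lay at percentile 100.0 and an unshifted one at 96.1. These libraries were simulated with counting error only (dispersion 0). The false calls of the rule under differences between cultures are thus not known. For the PFI pair against the other two limma recovered 53% of 2-fold differences with a dispersion of 0.01 and 2% with 0.04, and 95% and 59% of 4-fold ones, with 8 and 12 false calls.

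Alternatives tried were TMM scaling (30% of M and 5% of A values trimmed), library totals, limma-voom on recovered reads, no filter on low counts, a mean count of at least 50, pseudocounts of 0.5 and 10, an estimated list correlation, count minimums of 100 and none for the library ratios, genes chosen by the additive test for the comparison of pairs, no compound term, leaving out each library, and leaving out both libraries of a compound. The test of 1 pair against the others, the pseudocounts, the leaving out of both libraries of a compound, and library totals for the additive fit, the lists and the pairs were chosen after seeing the data. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.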

Results

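The data were 6 RNA-seq libraries, 1 for each of 6 groups, from cells labelled as the motor-neuron-like line NSC-34, a fusion of mouse neuroblastoma and spinal cord cells. The labels nevertheless gave the organism as human and every gene identifier in the tables was human. The groups were an untreated control, the compounds NaPhen and PFI alone (10 µM, 48 h), the peptide PR20 alone (5 µM, 24 h), and each compound (10 µM, 24 h) followed by PR20 (5 µM, 24 h). PR20 is a proline-arginine dipeptide repeat of the kind made from the repeat expansion linked to familial amyotrophic lateral sclerosis (ALS). NaPhen (sodium phenylbutyrate) inhibits histone deacetylases, and PFI (PFI-1) inhibits the BET bromodomain proteins that read acetylated histones. The libraries held 15339615 reads (control), 13881275 (NaPhen), 13953237 (PFI), 15148911 (PR20), 13483930 (PR20-NaPhen) and 13308986 (PR20-PFI), recovered from the deposited normalized counts. Between 22041 genes (PFI) and 24571 genes (PR20-NaPhen) had a count above 0, and 16269 genes were tested. Mitochondrial transcripts took 2.9% of the counts in the NaPhen library and 5.4% in the PR20-PFI library, with 4.7% in the control. With 1 library per group no spread between replicates could be measured, nothing stated that the libraries came from separate cultures, and the intervals of fold differences between single libraries cover counting error only.

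The first comparison asked which genes the peptide changed, over 3 pairs of libraries with and without PR20 (no compound, NaPhen, PFI). Replication-cluster histone genes made up 5 of the 8 largest rises. HIST1H2BF, which rose the most among these 8 (ENSG00000277224.2, GRCh38 chromosome 6, 26199520 to 26200715), rose by 3.06 ± 0.23 on the log2 scale (SE), by 2.79, 3.30 and 3.09 in the 3 pairs, with a limma adjusted p of 0.0024. HIST1H2AC (ENSG00000180573.9, chromosome 6, 26124145 to 26139116), the most abundant of them, rose by 2.39 ± 0.21, from a normalized count of 707.6 to 5104.3 without compound, from 560.7 to 3538.3 with NaPhen and from 1355.5 to 4288.4 with PFI. HIST1H3D (2.44 ± 0.26), HIST1H2BC (2.30 ± 0.21) and HIST1H2BE (2.19 ± 0.21) rose as well. The deepest fall was in EGR1 (ENSG00000120738.7, chromosome 5, 138465490 to 138469315), an immediate early transcription factor, which fell by 3.81 ± 0.30 on the log2 scale (limma adjusted p = 0.0024, lower in 3 of 3 pairs). Its normalized count went from 3229.4 to 501.0 without compound, from 4233.5 to 167.5 with NaPhen and from 8633.5 to 508.5 with PFI.

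The other genes among the 8 largest rises were the lipid phosphatase INPP5D (2.06 ± 0.26), and the loci CEP295NL (2.44 ± 0.53) and HOTAIRM1 (2.19 ± 0.44), which lie near or across other genes so that reads of the opposite strand cannot be excluded. The further falls among the 8 largest were in the prostaglandin transporter SLCO2A1 (-2.61 ± 0.35), the p53 relative TP73 (-2.34 ± 0.28), FAM19A5 (-2.27 ± 0.28), the glucuronyltransferase B3GAT1 (-2.22 ± 0.35), the sialyltransferase ST3GAL3 (-2.21 ± 0.49), CRYL1 (-2.08 ± 0.35) and the chemokine CXCL14 (-2.07 ± 0.36). Reads of the near-identical histone genes can be shared between copies, and ST3GAL3 no longer passed with limma-voom (-1.62).

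Targets of p53 rose as a group with PR20. Of 29 tested members 18 rose, 1 fell (PERP, -0.49 ± 0.12, chosen after its value was seen) and 10 did not pass, with 22 rising and 3 falling when adjusted over the list alone and a median log2 fold change of 0.89. TP53INP1 (ENSG00000164938.13, chromosome 8, 94925972 to 94949411), a stress-induced regulator of cell death and autophagy, rose by 1.97 ± 0.19, the death receptor EDA2R by 1.78 ± 0.15, the secreted stress cytokine GDF15 by 1.56 ± 0.32 and the cell-death gene BBC3 (PUMA) by 1.53 ± 0.18. Histone genes shifted upward too, with 16 of 29 rising and 1 falling (18 and 4 adjusted over the list alone) and a median of 1.35. With the preset correlation the camera adjusted p was 4.33e-07 for the p53 targets and 1.25e-06 for the histone genes. For both lists camera gave an adjusted p = 0.862 with an estimated correlation, and PERP (-0.44) did not pass when scaled by library totals.

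Genes of DNA replication fell almost throughout. Of 42 tested members 37 fell and none rose (40 fell adjusted over the list alone), and the median was -0.84. RRM2, a subunit of ribonucleotide reductase, fell by 1.63 ± 0.23 on the log2 scale, the cyclin CCNE2 by 1.45 ± 0.25, the transcription factor E2F1 by 1.40 ± 0.28 and the polymerase alpha subunit POLA2 by 1.33 ± 0.18. Mitosis genes moved the same way with a smaller count: 6 of 36 fell and none rose (16 fell adjusted over the list alone), among them AURKB (-0.91 ± 0.21), CDK1 (-0.91 ± 0.16) and MAD2L1 (-0.84 ± 0.19), and the median was -0.49. The fall rested on 2 of the 3 pairs, with medians of -0.73 without compound, -0.66 with NaPhen and 0.04 with PFI, where 23 members were higher and 13 lower. In the PFI library without PR20 mitosis genes were already at -0.48 against the control, with 35 of 36 lower. Camera placed DNA replication at an adjusted p of 5.81e-15 and mitosis at 5.66e-06. With camera the adjusted p = 0.862 with an estimated correlation for DNA replication and 0.894 for mitosis.

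Stress-response groups went different ways with PR20. Among 35 targets of ATF4, the transcription factor of the integrated stress response, 9 rose and none fell, also when adjusted over the list alone, with a median of 0.44. The median was 1.02 in the pair without compound (34 members higher, 1 lower, in the upper tail of random lists), -0.03 in the NaPhen pair (16 higher, 19 lower, percentile 64.8, and 0.01 with library totals) and 0.09 in the PFI pair (24 higher, 11 lower, percentile 99.9). Against the control the list was already at 0.52 in NaPhen and was at 0.71 in PR20-NaPhen. The ATF4 targets that rose with PR20 included DDIT4 (1.56 ± 0.38), GDF15, the stress-induced chromatin protein NUPR1 (1.53 ± 0.17) and ATF3 (1.39 ± 0.29). Of 21 cytosolic heat shock genes 4 fell and none rose (14 fell and 1 rose adjusted over the list alone; median -0.31). These were the near-identical HSPA1A (-1.17 ± 0.18) and HSPA1B (-0.94 ± 0.17), and HSPA8 (-0.58 ± 0.13) and BAG3 (-0.52 ± 0.14), both chosen after their values were seen. ATF4 targets had a camera adjusted p of 6.88e-04 and heat shock genes one of 8.16e-04. For ATF4 targets camera gave an adjusted p = 0.894 with an estimated correlation, and for heat shock genes 0.862. BAG3 (-0.47) did not pass when scaled by library totals.

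Smaller group shifts with PR20 touched glycolysis, the nuclear pore and the lysosome. Of 30 glycolysis and hypoxia genes 5 fell and none rose (6 fell and 1 rose adjusted over the list alone; median -0.27). These were the phosphofructokinases PFKL (-1.27 ± 0.21) and PFKP (-0.89 ± 0.13), the lactate carrier SLC16A3 (-0.72 ± 0.17), the glucose carrier SLC2A1 (-0.62 ± 0.13) and PFKFB3 (-0.46 ± 0.12, chosen after its value was seen). In the PR20 library against the control the glycolysis median was -0.12, within the random lists (percentile 15.3), while it lay in the lower tail in the NaPhen pair (percentile 0.1) and the PFI pair (percentile 0.0). Of 41 autophagy and lysosome genes 5 rose and none fell (5 rose and 1 fell adjusted over the list alone; median 0.16). These were GABARAPL1 (0.76 ± 0.16), NEU1 (0.59 ± 0.12), CTSA (0.52 ± 0.11), and HEXA (0.51 ± 0.12) and ATG14 (0.51 ± 0.13), both chosen after their values were seen. Of 42 genes of the nuclear pore and nucleocytoplasmic transport 5 fell and none rose (5 fell adjusted over the list alone; median -0.20). These were NUP210 (-0.74 ± 0.16), RANBP1 (-0.63 ± 0.16), TPR (-0.58 ± 0.12), CSE1L (-0.53 ± 0.14) and NUP62 (-0.45 ± 0.12, chosen after its value was seen). In the PFI pair the nuclear pore median was -0.08, within the random lists (percentile 38.8), while it lay in the lower tail in the pair without compound (percentile 0.3) and the NaPhen pair (percentile 0.1). By camera the adjusted p was 0.00206 for glycolysis, 0.0136 for autophagy and 0.00206 for the nuclear pore. For these 3 lists camera gave an adjusted p = 0.862 with an estimated correlation, and RANBP1 (-0.58), CSE1L (-0.48), NUP62 (-0.40) and PFKFB3 (-0.41) did not pass when scaled by library totals.

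ALS-linked genes and RNA-binding proteins showed no shift as a list with PR20 (32 tested, camera adjusted p = 0.818). The nuclear matrix protein MATR3 (0.91 ± 0.17, for ENSG00000280987.4, the more abundant of 2 identifiers with this symbol) and the kinesin KIF5A (0.91 ± 0.18) rose, while SOD1 (-0.59 ± 0.14) and PFN1 (-0.59 ± 0.13, chosen after its value was seen) fell. Markers of motor neurons (2 of 24 rose, 2 fell, camera adjusted p = 0.818), of fibroblasts and matrix (1 of 25 rose, 2 fell, 0.655), of glia (1 of 7 rose, 0.950) and of neuroblasts (1 of 7 rose, 1 fell, 0.883) were not shifted either by this test.

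By limma on log2 normalized counts, with compound and PR20 as additive terms, 1808 of 16269 genes changed with PR20 at an adjusted p under 0.05. Of these 716 rose and 1092 fell (39.6% rising), 643 of them by at least 2-fold. In 3 of 3 pairs 1807 went in the same direction. Disagreement between pairs is the error of this fit, so that agreement is nearly fixed by the test and adds no support. Scaled by library totals, 750 rose and 677 fell (52.6% rising). Of 36 lists 18 passed with the preset correlation (6 up, 12 down) and 0 with an estimated correlation (smallest adjusted p 0.862). With every pair made of single libraries, the count depended on which pair was left out. Leaving out 1 library leaves its partner fitted exactly, so its pair drops out of the PR20 effect. The error is then the difference between the pairs left. Fewer genes passed without either library of the pair without compound or of the NaPhen pair, and more without either PFI library. Of the 57 PR20 calls named by gene, 1 held without the control, 1 without PR20, 16 without NaPhen and 19 without PR20-NaPhen. Limma called 0 genes with no filter on low counts (5183 at an unadjusted p under 0.05) and 0 with no compound term (1269 at an unadjusted p under 0.05).

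**Figure D1:**
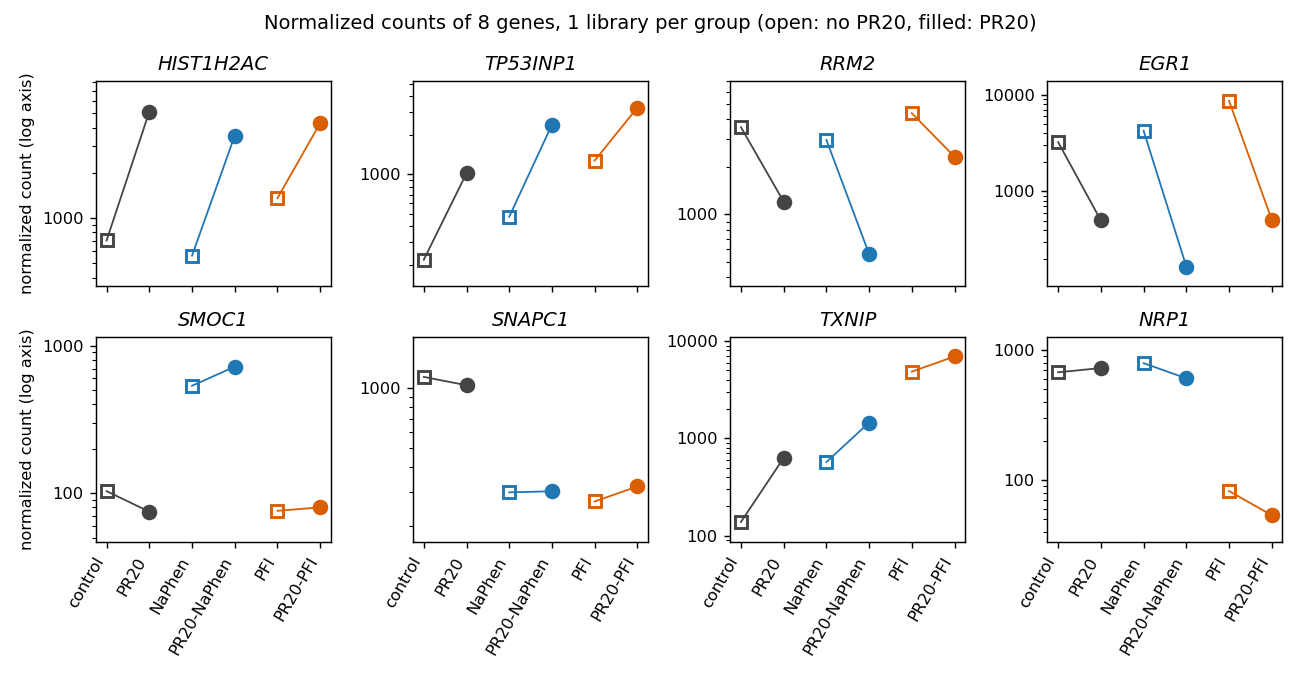
Normalized counts (log axis) of 8 named genes in each of the 6 libraries, 1 point per library, open without PR20 and filled with PR20. HIST1H2AC and TP53INP1 were higher and RRM2 and EGR1 lower with PR20 in 3 of 3 pairs, SMOC1 was higher in both NaPhen libraries, SNAPC1 was lower with either compound, and TXNIP was higher and NRP1 lower in both PFI libraries.

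The next comparison asked which genes NaPhen changed, over 2 pairs of libraries (without and with PR20) that differ in the stated hours of compound. SMOC1 (ENSG00000198732.10, chromosome 14, 69854131 to 70032366), a secreted calcium-binding protein, had the largest rise, 2.81 ± 0.25 (limma adjusted p = 0.010, higher in 2 of 2 pairs), from a normalized count of 103.2 to 535.3 without PR20 and from 74.9 to 720.8 with it. The scavenger receptor COLEC12 (2.74 ± 0.35), the unconventional myosin gene MYO15B (2.67 ± 0.38), the long non-coding RNA MIAT (2.48 ± 0.34), the selenium carrier SELENOP (2.44 ± 0.23), GDF15 (2.41 ± 0.40), ANO9 (2.28 ± 0.32) and the Wnt-pathway ubiquitin ligase RNF43 (2.24 ± 0.26) rose as well. SNAPC1 (ENSG00000023608.4, chromosome 14, 61762357 to 61796428), part of the complex that transcribes small nuclear RNA, fell by 1.86 ± 0.17 on the log2 scale (limma adjusted p = 0.010, lower in 2 of 2 pairs). Further falls were in MARCH4 (-2.13 ± 0.30), the oxidized-lipoprotein receptor OLR1 (-2.08 ± 0.41), the chemokine receptor ACKR3 (-1.91 ± 0.28), the aldehyde oxidase AOX1 (-1.88 ± 0.34), the tubulin TUBA4A (-1.86 ± 0.33), the smooth-muscle protein TAGLN (-1.78 ± 0.34) and the phosphatase DUSP1 (-1.75 ± 0.29).

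Interferon-stimulated genes shifted upward and heat shock genes downward with NaPhen. Of 30 interferon-stimulated genes 4 rose and none fell (16 rose adjusted over the list alone; median 0.82). These were the antiviral genes OASL (1.70 ± 0.29), IFI44 (1.58 ± 0.28), IFIT3 (1.45 ± 0.23) and IFIT2 (1.40 ± 0.28, chosen after its value was seen). BST2 had a log2 fold change of 1.45 ± 0.42 and did not pass. Of 21 cytosolic heat shock genes 5 fell and none rose (17 fell adjusted over the list alone; median -0.63). These were HSPB8 (-1.03 ± 0.21), CHORDC1 (-0.98 ± 0.17), HSPH1 (-0.84 ± 0.14), the mitochondrial chaperone HSPD1 (-0.79 ± 0.14) and HSP90AA1 (-0.78 ± 0.15, chosen after its value was seen). By camera the adjusted p was 1.22e-08 for the interferon list and 1.49e-08 for the heat shock list. For both, camera gave an adjusted p = 0.611 with an estimated correlation.

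Genes of ribosome biogenesis and of the proteasome were lower with NaPhen. Of 51 nucleolar gene identifiers (50 symbols) 4 fell and none rose (32 fell adjusted over the list alone; median -0.47). Among them were LYAR (-0.91 ± 0.17), UTP20 (-0.82 ± 0.16) and the helicase DDX21 (-0.80 ± 0.15), with NOLC1 (-0.69 ± 0.14) chosen after its value was seen. Of 35 proteasome subunits 4 fell and none rose (23 fell adjusted over the list alone; median -0.45). These were PSMD14 (-0.77 ± 0.16), PSMD12 (-0.72 ± 0.14), PSMD1 (-0.68 ± 0.14) and PSMD11 (-0.67 ± 0.13). The nucleolar list had a camera adjusted p of 9.94e-12 and the proteasome one of 3.90e-10. In the nucleolar list camera gave an adjusted p = 0.611 with an estimated correlation, and in the proteasome 0.612. Nuclear pore genes had no member past the test over all genes, but 21 of 42 fell adjusted over the list alone (median -0.41, camera adjusted p = 1.22e-08). For the nuclear pore camera gave an adjusted p = 0.611 with an estimated correlation. DNA replication genes were lower too (median -0.43), with 1 of 42 falling and none rising, also when adjusted over the list alone. Their camera adjusted p was 1.62e-05, and 0.857 with an estimated correlation.

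Transcripts of the mitochondrial genome fell with NaPhen, 3 of 15 over all genes (11 adjusted over the list alone; median -0.73). These were MT-ND4L (-1.05 ± 0.19), MT-CO1 (-0.91 ± 0.18) and MT-CYB (-0.82 ± 0.17). Mitochondrial genes took 2.9% of all counts in NaPhen and 3.8% in PR20-NaPhen, against 4.7% in the control and 5.0% in PR20. Chaperones of the endoplasmic reticulum shifted upward, with 4 of 21 rising and none falling (7 and 1 adjusted over the list alone; median 0.36). These were HERPUD1 (0.92 ± 0.14), CRELD2 (0.88 ± 0.17) and, chosen after their values were seen, the ubiquitin ligase SYVN1 (0.70 ± 0.14) and EDEM1 (0.69 ± 0.14), all of which take part in handling misfolded proteins. Of 41 autophagy and lysosome genes 4 rose and none fell (10 rose adjusted over the list alone; median 0.21). Among them were WIPI1 (0.90 ± 0.16), GRN (0.81 ± 0.16) and NPC2 (0.76 ± 0.14). Mitochondrial transcripts had a camera adjusted p of 7.49e-06, the chaperones one of 5.03e-04 and autophagy one of 0.00203. For these 3 lists camera gave an adjusted p = 0.611 with an estimated correlation.

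The list of genes known to rise with histone deacetylase inhibitors was not shifted past the test with NaPhen (camera adjusted p = 0.0966, median 0.21). Against the control its median was 0.25 in the NaPhen library, with 15 members higher and 6 lower, and 0.41 in the PR20-NaPhen library. Both lay in the upper tail of random lists. The list lay in the upper tail too in PFI (0.59), PR20 (0.27) and PR20-PFI (0.5), so this place was not particular to NaPhen. With NaPhen TXNIP (1.62 ± 0.32) and TP53INP1 (1.17 ± 0.23) rose and TAGLN fell among its 21 members, and CDKN1C stood at 1.27 ± 0.29 without passing. Of the list 4 rose and 2 fell adjusted over the list alone. Apoptosis regulators did not shift as a list (median -0.05, camera adjusted p = 0.663): 2 of 30 rose and none fell, also when adjusted over the list alone, the BCL2-family death genes BMF (2.15 ± 0.23) and BCL2L11 (0.76 ± 0.15). Inflammatory genes did not either (median 0.09, camera adjusted p = 0.247), with 2 of 16 rising and none falling, also when adjusted over the list alone, the chemokines CCL5 (2.04 ± 0.39) and CCL2 (1.99 ± 0.29). Of 35 ATF4 targets 2 rose and none fell, also when adjusted over the list alone, GDF15 and DDIT3 (1.29 ± 0.19), and the list did not pass (median 0.11, camera adjusted p = 0.446). Motor neuron markers passed upward with NaPhen (median 0.35, camera adjusted p = 0.0382). Of 24 members 1 rose and none fell (3 rose adjusted over the list alone). Their camera adjusted p was 0.611 with an estimated correlation and 0.0958 with library totals.

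By limma 346 of 16269 genes changed with NaPhen, 246 rising and 100 falling (71.1% rising), 226 by at least 2-fold. In 2 of 2 pairs 346 went in the same direction, which the test nearly fixes. Scaled by library totals, which moved the median gene by 0.14 in the NaPhen library and 0.18 in the PR20-NaPhen library against the control, 429 rose and 47 fell (90.1% rising). Of 36 lists 17 passed (5 up, 12 down) and 0 with an estimated correlation (smallest adjusted p 0.611, camera). Without the control library limma called 0 genes (2599 at an unadjusted p under 0.05), and 0 without PR20 (1557 at an unadjusted p under 0.05). It called 14 without NaPhen, 25 without PR20-NaPhen, 2228 without PFI, 2165 without PR20-PFI, 572 with voom weights and 0 with no filter on low counts (4355 at an unadjusted p under 0.05). Several calls lay close to the threshold: OLR1 (-2.07), HSPB8 (-1.02), UTP20 (-0.80), PSMD14 (-0.76), PSMD1 (-0.67), PSMD11 (-0.66), EDEM1 (0.70), HSP90AA1 (-0.77), NOLC1 (-0.68), MT-CO1 (-0.89) and MT-CYB (-0.81) did not pass with TMM scaling, and HSPD1 (-0.65), LYAR (-0.77), DDX21 (-0.66) and PSMD12 (-0.58) did not with library totals. GRN (0.81) did not pass with a pseudocount of 0.5. Of the 50 NaPhen calls named by gene, 0 held without the control, 0 without PR20, 4 without NaPhen and 7 without PR20-NaPhen.

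More genes passed the test with PFI than with PR20 or NaPhen, again measured over 2 pairs with different stated hours of compound. TXNIP (ENSG00000265972.5, chromosome 1, 145992435 to 145996600), an inhibitor of thioredoxin and of glucose uptake, rose by 4.29 ± 0.32 (limma adjusted p = 7.7e-05, by 5.13 and 3.46 in the 2 pairs). Among the 8 largest rises were the neuronal genes BAIAP3 (3.92 ± 0.23), MAP2 (3.49 ± 0.19) and BSN (3.30 ± 0.33), the protease HTRA1 (3.32 ± 0.26), SELENOP (3.30 ± 0.23), and PRAMEF12 (3.77 ± 0.32) and ZDHHC11B (3.16 ± 0.46), which have close copies in the genome. GPR1 (ENSG00000183671.12, chromosome 2, 206175316 to 206218047), a chemerin receptor gene, had 0 reads in both PFI libraries and normalized counts of 125.8 in the control and 162.7 in PR20, which makes the PFI library at least 38.1-fold lower than the control against a floor of 3 reads. TNFRSF8 (-6.10 ± 0.36), LCTL (-6.09 ± 0.47), MYOSLID (-5.91 ± 0.74), the vitamin D hydroxylase CYP24A1 (-5.86 ± 0.49), TMEM52B (-5.65 ± 0.35), ABCC9 (-5.64 ± 1.09) and OLR1 (-5.61 ± 0.41) fell to counts near 0, so that their fitted sizes depend on the pseudocount of 1 and are no bounds.

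Genes known to rise with BET inhibitors rose with PFI: 10 of 12 passed and none fell (11 rose adjusted over the list alone), with a median of 1.95, TXNIP first, and SERPINI1 at 2.61 ± 0.28, HIST1H2BC at 2.12 ± 0.26 and HIST2H2BE at 2.08 ± 0.19. Of the 29 histone genes, which share 6 members with that list, 18 rose and none fell (20 adjusted over the list alone), with a median of 1.25 and H2AFJ (2.97 ± 0.15) and HIST1H2BE (2.33 ± 0.25) ahead. The BET list had a camera adjusted p of 3.36e-05 and the histone genes one of 3.94e-08. For the BET list camera gave an adjusted p = 0.749 with an estimated correlation, and for the histone genes 0.733. The BET list rose with PR20 as well, 7 of 12 rising and none falling (8 adjusted over the list alone; median 1.35), with a camera adjusted p of 2.37e-05 and an adjusted p = 0.862 with an estimated correlation. Against the control its median was 1.86 in the PFI library and 1.32 in the PR20 library, both in the upper tail of random lists. Genes known to fall with BET inhibitors did not shift past the test (camera adjusted p = 0.0926, median -0.93). Against the control their median was -0.89 in the PFI library and -1.05 in the PR20-PFI library, both in the lower tail of random lists (percentile 0.0). Of the 19 members 9 fell, led by the cytokine receptor IL7R (-4.79 ± 0.34), with FOSL1 (-2.03 ± 0.39) and E2F2 (-1.16 ± 0.20). The 3 that rose were JUNB (1.45 ± 0.39) and, chosen after their values were seen, ID2 (0.94 ± 0.25) and CCND1 (0.67 ± 0.16). Adjusted over the list alone, 10 fell and 3 rose.

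Part of the lipid synthesis genes rose with PFI. Of 23 genes of cholesterol synthesis and uptake 11 rose, 12 did not pass and none fell, also when adjusted over the list alone (median 0.44). Among them were the sterol sensor INSIG1 (2.40 ± 0.19), STARD4 (1.44 ± 0.14), lanosterol synthase LSS (1.42 ± 0.22) and IDI1 (1.22 ± 0.22). Of 13 genes of fatty acid synthesis 8 rose, 5 did not pass and none fell, with the same counts adjusted over the list alone (median 0.53). Among them were the desaturase FADS2 (1.94 ± 0.25), the regulator SREBF1 (1.62 ± 0.22), fatty acid synthase FASN (1.33 ± 0.21) and SCD (1.25 ± 0.17). Cholesterol genes had a camera adjusted p of 0.00599 and fatty acid genes one of 0.0228. For both, camera gave an adjusted p = 0.892 with an estimated correlation. In the PFI library against the control both medians lay within the random lists (cholesterol 0.30, percentile 95.7; fatty acid 0.35, percentile 92.7), and in the PR20-PFI library both lay in the upper tail (0.34, percentile 98.9, and 0.42, percentile 98.6).

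Autophagy, antioxidant and secretory chaperone genes were also higher with PFI. Of 41 autophagy and lysosome genes 21 rose and 3 fell (25 and 4 adjusted over the list alone; median 0.58). The cargo receptor SQSTM1 (2.46 ± 0.14), the sialidase NEU1 (1.81 ± 0.15) and the kinase ULK1 (1.46 ± 0.15) rose. TFEB (-1.83 ± 0.23), a transcription factor of this programme, fell, with CTSZ (-0.79 ± 0.14) and ATG3 (-0.45 ± 0.15), both chosen after their values were seen. Of 24 NRF2 targets 13 rose and 3 fell (17 and 3 adjusted over the list alone; median 0.72). SQSTM1 and the ferritin chain FTL (1.43 ± 0.15) rose, and the cystine carrier SLC7A11 (-1.60 ± 0.35), MGST1 (-1.23 ± 0.20) and GSTA4 (-0.63 ± 0.15, chosen after its value was seen) fell. Of 21 chaperones of the endoplasmic reticulum 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.46). MANF (1.41 ± 0.17), DNAJB9 (1.32 ± 0.21) and EDEM1 (1.25 ± 0.14) rose and SSR3 (-0.65 ± 0.16, chosen after its value was seen) fell. Autophagy genes had a camera adjusted p of 4.79e-05, NRF2 targets one of 0.00231 and the chaperones one of 0.00231. For autophagy camera gave an adjusted p = 0.749 with an estimated correlation, for NRF2 targets 0.839 and for the chaperones 0.749.

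Matrix and nucleolar genes were lower with PFI. Of 25 fibroblast and matrix markers 15 fell and 6 rose (16 and 6 adjusted over the list alone; median -1.24). The largest falls were in the collagens COL3A1 (-3.32 ± 0.36) and COL1A1 (-2.88 ± 0.20), the collagen cross-linking enzyme LOX (-2.96 ± 0.17) and the receptor PDGFRB (-2.43 ± 0.20). Of 51 nucleolar gene identifiers (50 symbols) 29 fell and none rose (30 fell adjusted over the list alone; median -0.52), among them NOP16 (-1.36 ± 0.23), EMG1 (-1.29 ± 0.17), UTP20 (-1.23 ± 0.16) and PPAN (-1.16 ± 0.28). Of 35 ATF4 targets 14 fell and 1 rose, also when adjusted over the list alone (median -0.63). NUPR1 (-2.34 ± 0.21), GDF15 (-1.68 ± 0.40) and SLC7A11 fell, and DDIT3 (1.93 ± 0.19), a stress-induced transcription factor, rose. Matrix markers had a camera adjusted p of 0.0251, nucleolar genes one of 1.04e-05 and ATF4 targets one of 0.0474. For matrix markers and ATF4 targets camera gave an adjusted p = 0.942 with an estimated correlation, and for nucleolar genes 0.892. With library totals the camera adjusted p of ATF4 targets was 0.0572. In the PFI library against the control the ATF4 median was -0.10, with 14 members higher and 21 lower and within the random lists (percentile 9.4). It was 1.02 in the PR20 library and -0.04 in the PR20-PFI library.

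ALS-linked genes and RNA-binding proteins shifted upward with PFI, 9 of 32 rising and 2 falling, also when adjusted over the list alone (median 0.28). SQSTM1, the microtubule protein MAPT (2.21 ± 0.19) and the lysosomal growth factor GRN (1.42 ± 0.16) rose, and TUBA4A (-3.82 ± 0.33) and, chosen after its value was seen, TARDBP (-0.42 ± 0.14) fell. This list had a camera adjusted p of 0.0455. It had a camera adjusted p = 0.749 with an estimated correlation, 0.104 at a mean count of at least 50 and 0.0533 with library totals. In the PFI library against the control its median was 0.20, within the random lists (percentile 87.9). Motor neuron markers did not shift as a list (camera adjusted p = 0.279, median 0.56), with 9 of 24 rising and 5 falling (10 and 5 adjusted over the list alone). Against the control their median was 0.54 in the PFI library and 0.58 in the PR20-PFI library, both in the upper tail of random lists. MAP2, the synapsin SYN1 (2.82 ± 0.37) and MAPT rose, and the homeobox gene HOXC8 fell by 3.87 ± 0.25 on the log2 scale. Glial markers (2 of 7 rose, 3 fell, camera adjusted p = 0.535) did not shift either.

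By limma 6144 genes changed with PFI, 2853 rising and 3291 falling (46.4% rising), 3411 by at least 2-fold. In 2 of 2 pairs 6144 went in the same direction, which the test nearly fixes. Of 36 lists 12 passed (9 up, 3 down) and 0 with an estimated correlation (smallest adjusted p 0.733, camera). Limma called 3032 genes without the control library, 2417 without PR20 and 2148 with no filter on low counts. Of the 70 PFI calls named by gene, 57 held without PR20, 64 without the control, 66 without PFI, 67 without PR20-PFI, 68 without NaPhen and 68 without PR20-NaPhen.

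**Figure D2:**
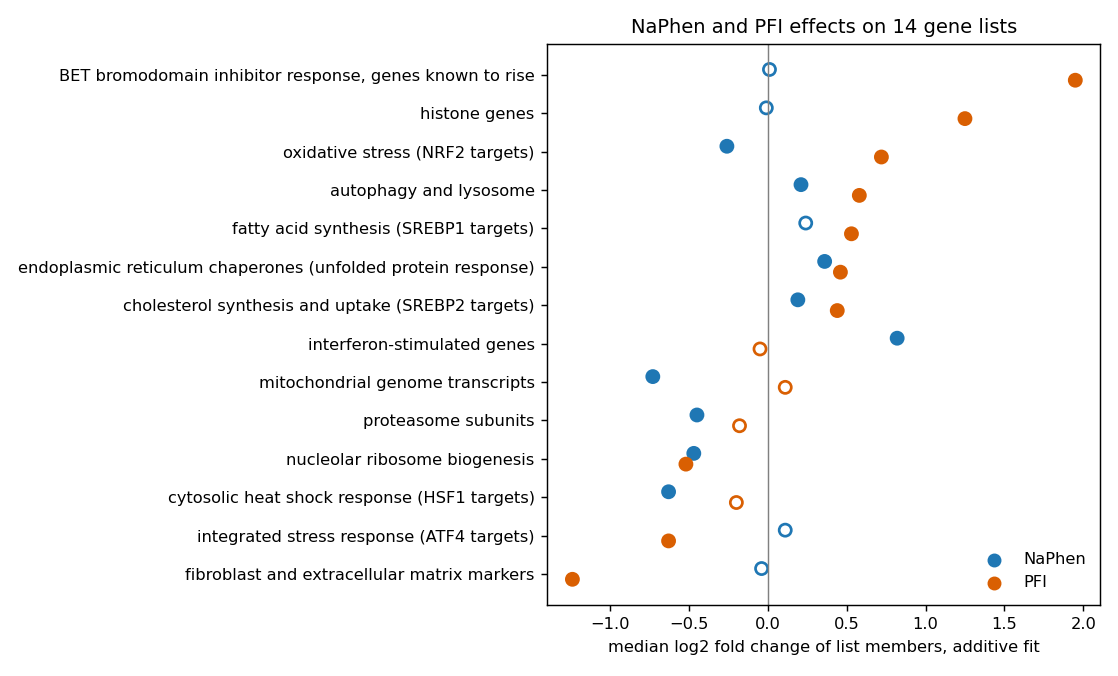
Median additive-fit log2 fold change of 14 gene lists with NaPhen and with PFI, 1 point per list and compound, filled where the camera adjusted p with the preset correlation was under 0.05 and open where it was not. Histone genes and genes known to rise with BET inhibitors lay at 1.25 and 1.95 with PFI, and interferon-stimulated genes at 0.82 and heat shock genes at -0.63 with NaPhen.

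Set against each other, the compounds differed in 5892 genes by limma, 3135 higher with NaPhen and 2757 higher with PFI (53.2% higher with NaPhen). With library totals 4190 were higher with NaPhen and 1360 with PFI (75.5% higher with NaPhen). GPR1 (6.42 ± 0.39), LCTL (5.77 ± 0.47) and the dopamine receptor DRD1 (5.68 ± 0.40) were highest with NaPhen relative to PFI and had normalized counts of 8.8 or less in the PFI libraries. PRAMEF12 (-3.90 ± 0.32), BSN (-3.14 ± 0.33), TRIM49B (-3.04 ± 0.38) and the histone gene HIST1H3H (-2.78 ± 0.22) were highest with PFI relative to NaPhen. Limma called 2987 genes without the NaPhen library, 2442 without PR20-NaPhen and 1603 with no filter on low counts. The compound effects share their reference libraries, control and PR20, which by itself gives a correlation of 0.5 across genes in simulated data with no effects. The observed correlation was 0.30 (Pearson) and 0.31 (Spearman), with a covariance of 0.168 against 0.048 simulated, and genes are not independent replicates. Of the genes that rose with NaPhen 133 also rose with PFI (43.1 expected if the calls were independent), 67 fell with both (20.2 expected), 35 rose with NaPhen and fell with PFI (49.8 expected) and 4 the reverse (17.5 expected). The part of the excess that comes from the shared libraries cannot be separated.

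Each treated library was also set against the control, which compares single libraries and not conditions. In the PR20 library the glutathione-degrading enzyme CHAC1 was 9.20-fold higher (95% counting interval 7.23 to 11.9), DDIT4 8.36-fold, ZFAS1 7.92-fold and HIST1H2AC 7.21-fold. RHBDL3 was 10.3-fold lower (ratio interval 0.0732 to 0.126), CXCL14 9.72-fold, TP73 7.73-fold, ATP2A3 6.58-fold and EGR1 6.45-fold. The secreted glycoprotein CHI3L1 went from 8 reads in the control to 128 with NaPhen (ratio interval 7.90 to 37.9). The fucosyltransferase FUT1 was 15.2-fold higher with NaPhen, IGFL4 11.4-fold, CCL24 9.59-fold and the integrin ITGB3 7.38-fold. The thyroid deiodinase DIO2 was 7.39-fold lower, the protease MMP3 6.36-fold, OLR1 6.27-fold, AOX1 5.49-fold, and ACKR3 had a log2 ratio of -2.38. With PFI alone TXNIP was 35.2-fold higher (29.8 to 41.7) and, from 5 or fewer control reads, CXCL8 41.3-fold (15.8 to 154), CCL20 38.5-fold (16.1 to 120), CALB1 43.8-fold (14.6 to 215) and PI3 83.2-fold (22.6 to 694). TNFRSF8 was 56.7-fold lower with PFI from 4 reads, and OLR1 (ratio interval 0.00217 to 0.0311, 3 reads), TMEM52B (0.00262 to 0.0378, 3 reads) and GALNT15 (0.000239 to 0.0541, 1 read) were at the limit of detection.

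In the PR20-NaPhen library the interferon gene RSAD2 was 30.7-fold higher than in the control (12.9 to 95.8), CD180 27.2-fold, GDF15 23.2-fold and FUT1 15.2-fold, and COLEC12 had a log2 ratio of 3.70. EGR1 was 19.3-fold lower, OLR1 13.8-fold, TUBA4A 7.84-fold, TP73 7.80-fold and GPER1 6.80-fold. In the PR20-PFI library TXNIP was 50.4-fold higher (42.8 to 59.7), HIST1H2BF 34.8-fold, HIST1H2BE 24.1-fold, HIST1H2BC 20.1-fold and the mitochondrial coactivator PPARGC1A 19.7-fold. MYOSLID and GPR1 had 0 reads there (at least 45.9-fold and at least 38.2-fold lower than the control), and CYP24A1 (ratio interval 0.000397 to 0.0119, 2 reads), LCTL (6.95e-05 to 0.0154, 1 read) and OLR1 (8.87e-05 to 0.0197, 1 read) were at the limit of detection. List medians placed among 10000 random lists of like expression were computed for the same libraries. Interferon-stimulated genes were at 0.80 in NaPhen and 0.92 in PR20-NaPhen, ATF4 targets at 0.52 in NaPhen, 1.02 in PR20 and 0.71 in PR20-NaPhen, and histone genes at 1.2 in PFI, 1.31 in PR20 and 2.58 in PR20-PFI, all log2 ratios to the control in the upper tail of the random lists. Heat shock genes were at -0.65 in NaPhen, -0.35 in PFI, -0.36 in PR20, -1.02 in PR20-NaPhen and -0.59 in PR20-PFI, all in the lower tail. Matrix markers were at -0.96 in PFI and -1.08 in PR20-PFI, also in the lower tail. Medians near 0 reached a tail too. In NaPhen p53 targets were at 0.04 (percentile 98.9) and nuclear-encoded respiratory chain genes at 0.02 (percentile 99.8), where random lists centred at -0.12. A place in a tail thus does not by itself show a shift with the treatment.

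By a rule of at least 2-fold with a counting interval that excludes 1.5-fold, 1163 genes differed between PR20 and control (501 higher, 662 lower), and 525 between NaPhen and control (343 higher, 182 lower). The rule counted 2492 between PFI and control (989 higher, 1503 lower), 2052 between PR20-NaPhen and control (1186 higher, 866 lower) and 3005 between PR20-PFI and control (1217 higher, 1788 lower). Scaled by library totals the split was 516 higher and 120 lower in NaPhen (81.1% against 65.3% higher) and 1658 higher and 519 lower in PR20-NaPhen (76.2% against 57.8%). With a minimum mean count of 100 in place of 20 the counts were 769 for PR20, 318 for NaPhen, 1609 for PFI and 1366 for PR20-NaPhen. The authors' DESeq2 tables for the same 5 comparisons held 0 genes with an adjusted p under 0.05. At an unadjusted p under 0.05 they held 94 genes for PR20, 18 for NaPhen, 513 for PFI, 373 for PR20-NaPhen and 1034 for PR20-PFI.

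The last comparison asked whether the PR20 response differed with a compound present, which is the question of a screen for compounds that limit dipeptide toxicity. It used 3 pairs that share no library: PR20 against control, PR20-NaPhen against NaPhen and PR20-PFI against PFI. The PR20 response of genes selected in either of the other pairs was smaller in the PFI pair. Among the 1163 genes selected in the pair without compound, where the median response was 1.36, it was 1.07 in the NaPhen pair (95% interval over resampled genes 1.02 to 1.11) and 0.36 in the PFI pair (0.34 to 0.40), in the direction of the selecting pair. Among 1356 genes selected in the NaPhen pair (708 up, 648 down, median 1.37) it was 1.02 without compound and 0.45 with PFI, a ratio of 0.45 (0.42 to 0.47). Among 348 genes selected in the PFI pair (median 1.45) it was 0.56 without compound and 0.94 with NaPhen, a ratio of 1.69 (1.40 to 2.04).

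**Figure D3:**
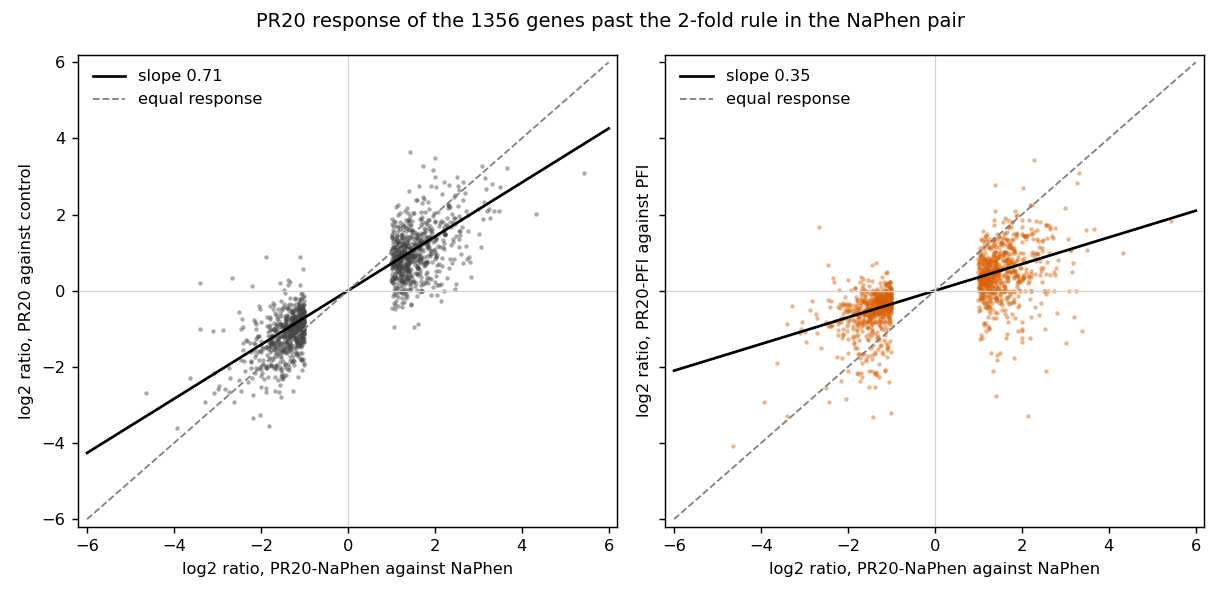
PR20 response (log2 ratio) of the 1356 genes selected in the NaPhen pair, measured in the pair without compound and in the PFI pair against the response in the NaPhen pair, 1 point per gene, with the fitted slope and a dashed line of equal response. The slope was 0.71 without compound and 0.35 with PFI.

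By gene group, p53 targets had a median response of 0.97 without compound, 1.12 with NaPhen and 0.48 with PFI, and DNA replication genes had -0.87, -1.25 and -0.42. Histone genes were at 1.31, 1.43 and 0.97. Mitosis genes were at -0.73 without compound and -0.66 with NaPhen, against 0.04 with PFI. Against the control mitosis genes were already at -0.48 in PFI (35 of 36 lower) and were at -0.42 in PR20-PFI. DNA replication genes were at -0.31 in PFI and -0.71 in PR20-PFI. ATF4 targets were at 1.02 without compound, -0.03 with NaPhen (percentile 64.8 among random lists, and 0.01 with library totals) and 0.09 with PFI (percentile 99.9). Against the control they were already at 0.52 in NaPhen (31 of 35 higher) and were at 0.71 in PR20-NaPhen. They were at -0.10 in PFI and -0.04 in PR20-PFI. The median near 0 with NaPhen thus does not mean that the targets were low. TP53INP1 followed its group with 2.21, 2.35 and 1.35, and RRM2 with -1.57, -2.40 and -0.92, whereas EGR1 was lower by a larger factor with either compound (-2.69 without, -4.65 with NaPhen, -4.08 with PFI). The PR20 response of DDIT4 was 3.06 without compound, 0.84 with NaPhen and 0.79 with PFI. These are ratios to the matched library of each pair, so they do not show that either compound lowered the level of DDIT4.

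**Figure D4:**
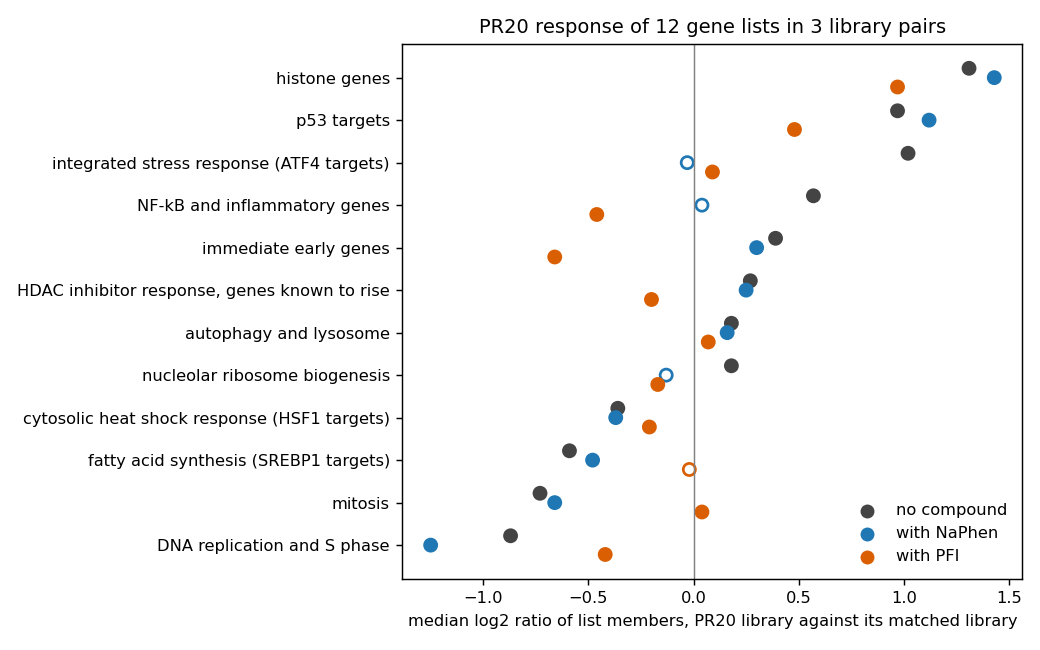
Median PR20 response (log2 ratio) of 12 gene lists in the pair without compound, the NaPhen pair and the PFI pair, 1 point per list and pair, filled where the median lay in the outer 2.5% of either tail of 10000 random lists and open where it lay within. Mitosis genes lay at -0.73 without compound and at 0.04 with PFI, and ATF4 targets at 1.02 without compound, -0.03 with NaPhen (0.01 with library totals) and 0.09 with PFI. Each point is a ratio to the matched library. Against the control mitosis genes were already at -0.48 in PFI, and ATF4 targets at 0.52 in NaPhen.

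Across 10942 genes the PR20 response correlated at 0.77 (Pearson) between the pair without compound and the NaPhen pair, at 0.43 with the PFI pair and at 0.56 between the NaPhen and PFI pairs, and its standard deviation was 0.55, 0.56 and 0.37. With genes selected by the additive limma test, the slopes for the PFI pair were 0.58 and 0.57 and the ratios to the other pairs 0.52 and 0.56. In each compound pair the stated hours of compound differed between the libraries.

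The response of 1 pair was also tested with limma against the mean of the other two, a test chosen after seeing the data that takes the difference between these other pairs as its error (1 residual degree of freedom). In the PFI pair 266 of 16269 genes differed (86 higher, 180 lower), with a smaller absolute response than in the other pairs for 159, a larger one for 107 and the opposite sign for 154. For the NaPhen pair limma called 0 genes (283 at an unadjusted p under 0.05), and for the pair without compound 0 (547 at an unadjusted p under 0.05). In those tests the error is the difference between the PFI pair and another pair, whose responses correlated at 0.43 and 0.56. For the PFI pair it is the difference between pairs that correlated at 0.77. The counts of 0 thus cannot show that only the PFI pair differed. Of the genes named above, HIST1H2AC differed in the PFI pair by -1.09 ± 0.26 (limma adjusted p = 0.032). TP53INP1 (-0.92 ± 0.27), RRM2 (1.07 ± 0.30), DDIT4 (-1.17 ± 0.48) and EGR1 (-0.41 ± 0.44) did not pass. By camera 7 of 36 lists passed for the NaPhen pair (1 up, 6 down). For the pair without compound 7 passed (6 up, 1 down). With an estimated correlation 0 passed for either. For the PFI pair 15 of 36 lists passed (6 up, 9 down) and 0 with an estimated correlation (smallest adjusted p = 0.718). The mitosis list had a median difference of 0.72 (camera adjusted p = 7.02e-14), DNA replication 0.70 (1.78e-11), p53 targets -0.65 (1.45e-05) and ATF4 targets -0.32 (0.00508), while histone genes did not pass (0.588). With an estimated correlation the adjusted p = 0.718 for mitosis, DNA replication and p53 targets and 0.931 for ATF4 targets. The ATF4 response of the PFI pair lay near that of the NaPhen pair, and in the pair without compound ATF4 targets stood apart by a median of 0.85 (camera adjusted p = 3.73e-18, and adjusted p = 0.875 with an estimated correlation). The count of 266 genes was 173 with TMM, 155 with library totals, 102 at a mean count of at least 50, 87 with limma-voom and 0 with no filter on low counts (2754 at an unadjusted p under 0.05).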

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

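Of the tests below, those of regression to the mean, of genes that PFI had moved and of the PFI pair against the other pairs were chosen only after their results were seen.

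A set of 5 gene lists had a median PR20 response that lay in opposite tails of 10000 random lists in pairs that differ by the compound. Mitosis genes were at -0.73 without compound, -0.66 with NaPhen and 0.04 with PFI. Immediate early genes were at 0.39 without compound, 0.30 with NaPhen and -0.66 with PFI. NF-kB and inflammatory genes were at 0.57 without compound and -0.46 with PFI. Genes known to rise with histone deacetylase inhibitors were at 0.27 without compound, 0.25 with NaPhen and -0.20 with PFI. Nucleolar ribosome biogenesis genes were at 0.18 without compound and -0.17 with PFI. These are ratios within each pair. Against the control the PFI library already lay at -0.48 for mitosis, 0.86 for immediate early genes and 0.64 for inflammatory genes. It lay at 0.59 for genes known to rise with histone deacetylase inhibitors and at -0.36 for nucleolar genes. The PR20-PFI library lay at -0.42, 0.22, 0.09, 0.50 and -0.52, in the same order. The PFI pair thus started from lists already moved with PFI alone. Tested as the PFI pair against the mean of the other two, 4 of these 5 lists passed by camera: mitosis (median difference 0.72, adjusted p 7.02e-14), immediate early genes (-1.16, 1.07e-10), inflammatory genes (-0.55, 2.8e-04) and genes known to rise with histone deacetylase inhibitors (-0.46, 0.00493). The nucleolar list did not pass (0.052). With an estimated correlation the 4 had an adjusted p = 0.718, in a test on 1 degree of freedom. Mitosis also passed by camera for the NaPhen pair (-0.33, 0.00163) and the pair without compound (-0.46, 2.81e-05). Immediate early (0.77, 8.6e-08), inflammatory (0.31, 0.013) and nucleolar genes (0.29, 1.03e-04) passed by camera for the pair without compound. With an estimated correlation these had an adjusted p = 0.928 (NaPhen pair) and 0.875 (no compound). Each pair is set against the mean of the other two, so a departure of 1 pair also moves the tests of the others. These passes thus cannot by themselves show which pair was set apart. For mitosis the pair without compound and the NaPhen pair lay close to each other (-0.73 and -0.66).

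By the same test the response of the PFI pair differed for DNA replication genes (median difference 0.70, camera adjusted p 1.78e-11), p53 targets (-0.65, 1.45e-05), ATF4 targets (-0.32, 0.00508) and 266 single genes by limma. With an estimated correlation these 3 lists had an adjusted p = 0.718, 0.718 and 0.931. The test takes the other two pairs to respond alike, which the ATF4 medians do not show (1.02 without compound, -0.03 with NaPhen and 0.09 with PFI): the PFI pair lay near the NaPhen pair, and the pair without compound stood apart (0.85, camera adjusted p 3.73e-18, and adjusted p = 0.875 with an estimated correlation). For DNA replication genes the NaPhen pair passed as well, in the other direction (-0.59, camera adjusted p 1.02e-12, and adjusted p = 0.928 with an estimated correlation). These results are tied, since each pair enters the mean that the other is set against. The medians were -0.87 without compound, -1.25 with NaPhen and -0.42 with PFI. Against the control DNA replication genes were already at -0.31 in PFI and were at -0.71 in PR20-PFI. ATF4 targets were already at 0.52 in NaPhen and were at 0.71 in PR20-NaPhen.

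Among genes chosen in the other pairs the PR20 response was smaller in the PFI pair. Genes that PFI had already moved could give this, but among the 315 genes chosen in the NaPhen pair whose log2 ratio of the PFI library to the control was within 0.3 of 0, the ratio of the median response with PFI to that without compound was 0.44 (0.39 to 0.49), which argues against it as the whole cause. This holds for those genes and does not cover the gene lists above, some of which PFI alone had moved. Shrinkage of chosen genes toward 0 is argued against by a ratio of 0.45 (0.42 to 0.47) in all 1356 genes chosen in the NaPhen pair, since it would act alike on both measured pairs. With genes chosen by the additive test the ratio was 0.56. That choice uses the measured pairs themselves, so this ratio cannot speak on shrinkage. What stays open is a lower exposure to the peptide in the PR20-PFI library, differences between the cultures behind single libraries, the different stated hours of PFI in that pair, and a weaker response of cells treated with PFI, which is a hypothesis: the test of the PFI pair (266 genes) compares 1 pair of libraries with 2 others and cannot part it from these.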

How the results depend on the processing

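The alternatives with other pseudocounts, with both libraries of a compound left out, and with library totals for the additive fit, the lists and the pairs were chosen after seeing the data, as was the test of the PFI pair against the other pairs with all its settings. No paired analysis was possible because the labels give no replicate numbers shared between groups and each group holds 1 library; the pairs of the additive fit come from its compound term. The planned edgeR and DESeq2 alternatives were not run, since the deposited table held normalized counts and count tests were not applied to the recovered reads. With TMM, a mean count of at least 50, pseudocounts of 0.5 and 10, and library totals, the limma counts for PR20, NaPhen, PFI and NaPhen minus PFI stayed within 1.5 times their main values; with limma-voom all but NaPhen did (572). With no low-count filter limma called 0 genes for PR20 (5183 at an unadjusted p under 0.05), 0 for NaPhen (4355 at an unadjusted p under 0.05), 2148 for PFI and 1603 for NaPhen minus PFI, and the cause was not tested. With no compound term it called 0 genes for PR20 (1269 at an unadjusted p under 0.05), where the compound differences enter the residual by construction.

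Leaving out 1 library gave between 1 gene (without control, and without PR20) and 4301 genes (without PFI) for PR20, between 0 (without control, 2599 at an unadjusted limma p under 0.05, and without PR20, 1557) and 2228 (without PFI) for NaPhen, between 2417 (without PR20) and 6251 (without PFI) for PFI, and between 2442 (without PR20-NaPhen) and 6000 (without PFI) for NaPhen minus PFI. Each such fit has 1 residual degree of freedom and assumes that the lone library of a group varies like the others. That lone library is fitted exactly, so for PR20 its pair drops out and the error is the difference between the remaining pairs. Without both PFI libraries limma called 4171 genes for PR20 and 2022 for NaPhen, and without both NaPhen libraries 124 for PR20; 1783 of the 1808 PR20 genes and 346 of the 346 NaPhen genes were among those called without the PFI libraries. Without the PFI libraries the error is only the difference between the pair without compound and the NaPhen pair, so a departure of the PFI pair no longer counts as error. The PR20 responses of those pairs correlated at 0.77, against 0.43 and 0.56 with the PFI pair. In the test of the PFI pair 266 genes departed from a shared response. That count was 173 with TMM, 155 with library totals, 87 with limma-voom, 102 at a mean count of at least 50 and 0 with no low-count filter (2754 at an unadjusted limma p under 0.05), and the cause was not tested; with pseudocounts it stayed within 1.5 times, and no library could be left out of a fit with 1 residual degree of freedom.

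With an estimated correlation camera passed 0 lists for PR20, 0 for NaPhen and 0 for PFI, with smallest adjusted p 0.862, 0.611 and 0.733. By construction that setting also tests on the 2 residual degrees of freedom of the fit, and lists with an estimated correlation below the preset 0.01 lost the call too, such as the histone genes (-0.018). Of the 108 list tests, 108 stayed on their side of the threshold with TMM, 103 with library totals and 101 at a mean count of at least 50. Of 186 log2 fold changes named by gene, 175 stayed on their side with TMM, 165 with library totals, 184 with limma-voom, 183 at a mean count of at least 50 and 54 with no low-count filter. None changed sign in any alternative run. For PR20, leaving out 1 library only drops a pair, which cannot turn the sign of a gene whose pairs agree. Pairs agreed for 1807 of the 1808 PR20 calls, so the kept signs say little there.

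With a count minimum of 100 fewer genes could be counted against the control: 318 for NaPhen, 1609 for PFI, 769 for PR20 and 1366 for PR20-NaPhen, while PR20-PFI, TMM, library totals and no minimum stayed within 1.5 times. That minimum moved slopes of the PR20 response to 0.30 for PFI with genes chosen without compound, to 0.77 (no compound) and 0.39 (PFI) with genes chosen with NaPhen, and to 0.45 (no compound) and 0.68 (NaPhen) with genes chosen with PFI. With genes chosen by the additive test the slopes were 0.99 and 0.58 chosen without compound, 0.87 and 0.57 with NaPhen, and 1.09 and 1.22 with PFI, and the ratios of medians 0.52, 0.56 and 1.07; the cause was not tested. TMM and library totals left the slopes and ratios within their intervals, and TMM left 55 of 55 list medians of library ratios within theirs. Library totals left 50 of 55: the others were heat shock (-0.84) and interferon-stimulated genes (1.1) in PR20-NaPhen against control, and p53 targets (0.55), nucleolar genes (-0.10) and nuclear pore genes (-0.01) in the PFI pair. Within its interval, the ATF4 median in the NaPhen pair went from -0.03 to 0.01. The depth of 13308986 to 15339615 reads limits the genes near 0, whose folds are bounds or wide intervals.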

Other observations

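Of the tests below, those of mouse reads and of cells in S phase were chosen only after their results were seen.

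Long non-coding RNA genes and protein-coding genes split differently with PR20: 143 long non-coding genes rose and 17 fell (1938 tested, median log2 fold change 0.23), against 513 and 1070 of 13516 protein-coding genes (median -0.04), and with PFI 193 long non-coding genes rose and 378 fell (median -0.17). The long non-coding genes had a median mean count of 23 against 435.2, and the difference between the classes was not tested. Apoptosis regulators did not shift as a list with PR20 (30 tested, camera adjusted p = 0.437), with 6 rising and 2 falling (7 and 3 adjusted over the list alone): the death genes HRK (2.04 ± 0.26), BBC3 (1.53 ± 0.18) and BAX (0.73 ± 0.11) rose by limma, and BID fell by 1.37 ± 0.18 on the log2 scale.

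Axon guidance genes moved both ways with PFI, 14 of 35 falling and 7 rising (15 and 7 adjusted over the list alone; median -0.50, camera adjusted p = 0.0630). Against the control their median was -0.46 in the PFI library (percentile 0.4 among random lists) and -0.75 in the PR20-PFI library (percentile 0.0). The semaphorins SEMA3E (-3.58 ± 0.36) and SEMA3A (-3.24 ± 0.32), the SEMA3A receptor NRP1 (-3.37 ± 0.21, chromosome 10, 33177492 to 33336262) and the ephrin EFNB3 (-2.62 ± 0.20) fell. Interferon-stimulated genes did not shift as a list with PFI (10 of 30 fell and 6 rose, 11 and 7 adjusted over the list alone; median -0.05, camera adjusted p = 0.763).

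The gene identifiers were human although the labels name a mouse hybrid line. Mouse reads aligned to the human genome are argued against by human genes with no mouse counterpart, of which 19 of 42 listed (45.2%, exact interval 29.8% to 61.3%) had a mean normalized count of 50 or more, IL32 with 1538.4 (chosen after its value was seen) among them. A human line, or a mixture with human cells, stays open, and no attempt was made to name a line. No biological explanation was tested.

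Of 29 histone genes 16 rose and 1 fell with PR20 (18 and 4 adjusted over the list alone), and their median was 1.31, 1.43 and 0.97 in the 3 pairs, with 8, 9 and 6 members lower. With an estimated correlation the camera adjusted p = 0.862. More cells in S phase is argued against by the median of the DNA replication list, -0.84 over 42 genes, and reads shared between copies are argued against by the summed count of 49 replication-cluster histone genes, which was 3.69-fold, 3.99-fold and 2.45-fold higher in the 3 pairs. A larger share of RNA without a poly(A) tail, which replication histone transcripts lack, cannot be told apart: the median of 19 small non-coding RNA genes was 0.05 with an interval of -0.02 to 0.33. The same sum was 2.91-fold higher in PFI than in the control and 0.88 of it in NaPhen. A change in histone transcripts caused by PR20 is a hypothesis that these libraries leave open.

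The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split gave 1808 genes with limma and the highest of the others 0, and 1 split gave as many as the real one, itself included.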
